A study of Mus musculus with 2 samples.

How the data were processed

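Total RNA from 2 mouse ES cell cultures, 1 control (DMSO) and 1 in which Daxx was deleted with 4-hydroxytamoxifen, was sequenced as TruSeq RNA libraries, per the labels' protocols. The deposited table holds RPKM values per transposable element family in both libraries, with the number of annotated copies. Per the file headers and the info sheet, the authors aligned the reads to mm9 with JAGuaR 2.1, which runs BWA and adds exon-exon junctions from Ensembl 67. BWA 0.7.10 and mm9 are also named in the submitters' processing notes. Per the info sheet, the RPKM values the authors deposited are scaled by the reads in exons of protein-coding genes, leaving out mitochondrial and ribosomal protein genes and the top 0.5% of exons by expression, and multi-mapped reads were kept for transposable elements. How a multi-mapped read was shared out, which overlap counted as a read of an element, which repeat annotation was used and whether strand was used are not given in the sources used here. Multi-mapped reads let young families with near-identical copies be counted, and they also let the LTR and the internal part of an element, or related families, hold the same reads. Because the scale is set by exonic reads of genes, a family's value also moves with that total.

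The control column was matched to the sample given DMSO, and the column named for 4-OHT to the sample given 4-hydroxytamoxifen, and 0 columns of other samples were present. The total reads per library are not given in the sources used here. Whole reads were sought in the low values: of 54 families with few expected reads, the ratios of 5 lay within 0.4% of a ratio of small whole numbers after the best common scaling, against a median of 6 in 100 jittered copies of the data, so depth was not recovered. No interval or detection limit is given for that reason. A value of 0 is reported only as listed at 0: 33 families were at 0 in both libraries, 22 in the control only and 7 in the Daxx-deleted library only.

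With 1 library per group no test was run and nothing was fitted. The log2 change is log2((Daxx-deleted + pseudocount) / (control + pseudocount)), which understates the change of low families. Before the data were examined, the pseudocount was set to 0.1 RPKM, the floor to a mean of 0.5 RPKM and the threshold to 2-fold. Since 21 of 634 families passed that floor, a second setting was added after the values were seen: pseudocount 0.001 RPKM, mean of at least 0.01 RPKM and at least 100 copies. Ratios in the text are quotients of the deposited values, with no pseudocount. The alternatives were pseudocounts of 0.01 and 1 RPKM, no floor, a floor of 5 RPKM, thresholds of 1.5-fold and 3-fold, subtraction of the median and the ratio of summed RPKM. Around the added setting they were pseudocounts of 0.0001, 0.01 and 0.1 RPKM, a floor of 0.05 RPKM, no minimum of copies and a minimum of 1000 copies.

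Families were grouped by name into lists written before the data were examined: IAP, ETn and MusD, MMERVK10C and RLTR10, RLTR9/13/17, class I ERV, MERVL, older ERVL, MaLR, mouse-specific LINE-1, older LINE-1 and SINE. The spelling of RLTRETN_Mm, the ETn LTR, was added to its list's pattern after the table was opened. Of all 21 lists, 10 had no member in the table: satellites, telomere repeats, DNA transposons, structural RNAs and the 6 gene lists, among them fibroblast markers for feeder cells. The table holds families and 0 of the genes on those lists, so the feeder share and Daxx were not analysed here. A list's median was placed among 10000 random lists of the same size, each member replaced by 1 of the 30 other families nearest in mean RPKM (10 at the preset floor). The percentile describes these libraries and is no p-value. Lists with under 3 families past a floor have no percentile.

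Families named in the text follow a rule set before the data were examined: the 12 highest and 12 lowest log2 changes at the preset floor, the 5 highest levels, and in each list the 3 highest levels and the largest change. Families outside this rule are marked where they appear. The percentile was tested on simulated data made from the 436 control levels. With an SD of 0.3 on the log2 scale, lists of 7 families raised 1.5-fold reached the upper 2.5% of random lists in 100% of 40 simulations, lists of 3 families in 90%, and unchanged lists of 7 and 3 families in 5% and 2.5%. With the SD of the 436 families themselves, 0.41, which was added after the values were seen, these shares were 80%, 47.5%, 0% and 7.5%. The simulated changes were independent between families and the lists were drawn at random. Members of a real list can hold the same reads, so these shares do not give the rate at which unchanged real lists would reach the upper 2.5%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Coordinates were not used, since the annotation at hand is of another build than mm9.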

Results

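RNA-seq was used to ask whether endogenous retroviruses (ERVs) become active when the histone chaperone Daxx is removed from mouse embryonic stem (ES) cells. Daxx deposits the histone variant H3.3 together with Atrx. The cells carried a Daxx gene flanked by loxP sites (Daxx fl/fl) and a tamoxifen-inducible Cre recombinase, on a mixed B6/129 background, and were grown on inactivated feeder cells. The Daxx-deleted culture received 4-hydroxytamoxifen (4-OHT) at 1 µM for 48 h and then recovered for 3 days, and the control culture received the solvent DMSO. Each condition was measured in 1 library, so no value has a replicate error and no p-value is given. The measured items were 634 families of transposable elements, of which 471 were LTR families, 122 were LINE families and 40 were SINE families. The remaining family, LTR82B, was listed as low complexity. Each family sums the reads of copies scattered over the genome, so a value belongs to a family and to no single locus. The levels were low: the median family had 0.0209 RPKM (reads scaled by length and by the exonic reads of the library) in the control and 0.0269 RPKM in the Daxx-deleted library. The depth of the libraries is unknown, so no counting error could be attached to the values. The level of Daxx itself was not analysed here, and the direction of each comparison therefore rests on the labels of the 2 libraries.

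The ERV families MERVL-int, MMERVK10C-int, IAPEz-int and IAPLTR1_Mm were higher in the Daxx-deleted library. Pairs of values are given with the control first. MERVL-int, the internal part of the ERV that is active in the 2-cell embryo, stood at 0.0198 and 0.101 RPKM, a ratio of 5.11. MMERVK10C-int stood at 0.0348 and 0.123 RPKM, a ratio of 3.54. IAPEz-int, the internal part of the intracisternal A-particle (IAP), an ERV whose new insertions cause mutations in mice, stood at 0.0736 and 0.201 RPKM, a ratio of 2.74. MMETn-int, the internal part of an ETn element and also a class II ERV, stood at 2.39 RPKM in the control and at 2.40 RPKM in the Daxx-deleted library.

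The size rule set before the data were examined did not reach most of these families. It asked for a mean of at least 0.5 RPKM and a 2-fold change with a pseudocount of 0.1 RPKM. Only 21 families (3.31%) reached that level, and 0 of them were 2-fold higher and 0 were 2-fold lower. Their median log2 change was -0.10. At that pseudocount the log2 changes of the low families are compressed: MERVL-int had 0.75, MMERVK10C-int 0.73, IAPEz-int 0.80 and IAPLTR1_Mm 0.94. A lower floor was therefore chosen after seeing the data. It kept the 436 families (68.8%) with a mean of at least 0.01 RPKM and at least 100 annotated copies, with a pseudocount of 0.001 RPKM, and the log2 changes given from here on use that pseudocount unless stated. At this floor 23 families were at least 2-fold higher in the Daxx-deleted library and 2, RLTR9A2 and HERVL74-int, were at least 2-fold lower. HERVL74-int, named after its value was seen, stood at 0.0229 and 0.00959 RPKM. Of the 436 families, 344 had a higher value in the Daxx-deleted library. The median family was higher by 0.18 on the log2 scale, and the quartiles of the families were 0.05 and 0.40. After that median was subtracted, 14 families were 2-fold higher and 3 were 2-fold lower. Among the 257 families with at least 1000 copies, 10 were 2-fold higher and 0 were 2-fold lower, and after subtraction the counts were 8 and 0.

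**Figure D1:**
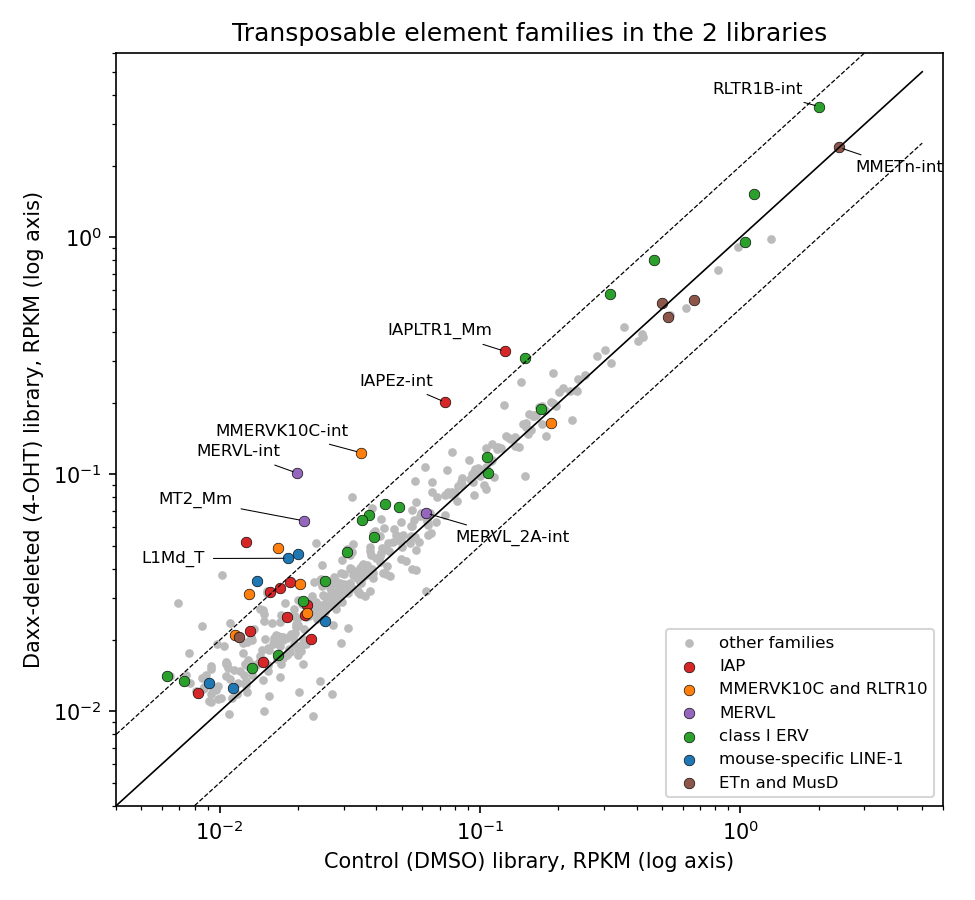
RPKM of each family in the control library (x axis) and the Daxx-deleted library (y axis), both on log axes, for the 436 families at the lower floor. Points are families, the solid line marks equal values and the dashed lines a 2-fold difference, and MERVL-int, MMERVK10C-int, IAPEz-int and IAPLTR1_Mm lie above the upper dashed line, and MMETn-int lies on the solid line.

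The IAP elements were compared as a list fixed before the data were examined. Of the 13 IAP families at the lower floor, 12 had a higher value in the Daxx-deleted library. With the pseudocount of 0.001 RPKM, 7 were higher by at least 1.5-fold and 3 by at least 2-fold. IAPLTR1a_Mm, named after its value was seen, had a ratio of 2.05 but a log2 change of 0.99 with that pseudocount. The list's median log2 change was 0.69, or 0.51 relative to the median family, and 11 of the 13 lay above that family. The median stood above every one of 10000 random lists of the same size and level (percentile 100). Over all 16 IAP families, with the pseudocount of 0.1 RPKM, it was 0.08, at percentile 96.5. IAPLTR1_Mm, an IAP long terminal repeat, stood at 0.125 and 0.330 RPKM, a ratio of 2.64. IAPEy-int stood at 0.0126 and 0.0521 RPKM, a ratio of 4.12, with 536 copies. IAPLTR2b, named after its value was seen because it was the only IAP family at this floor with a lower value, stood at 0.0224 and 0.0202 RPKM.

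The MMERVK10C and RLTR10 elements, class II ERVs, showed a similar shift. Of 7 families, 6 had a higher value, 5 by at least 1.5-fold and 3 by at least 2-fold, and 6 lay above the median family. The median log2 change of 0.83 (0.65 relative to the median family) lay at percentile 99.9 of the random lists. RLTR10C, an LTR of this list, stood at 0.0167 and 0.0487 RPKM, a ratio of 2.92. RLTR10-int, named after its value was seen as the remaining family past 2-fold, stood at 0.0130 and 0.0312 RPKM. RLTR10E, with the highest level of the list, had 0.187 RPKM in the control and 0.166 RPKM in the Daxx-deleted library.

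The MERVL list split within itself. MERVL-int and its LTR, MT2_Mm, were both higher, MT2_Mm standing at 0.0210 and 0.0637 RPKM, a ratio of 3.03. LTR65, a family of similar level with 165 copies, was named after its value was seen. It had a log2 change of -1.10 relative to the median family, against 1.38 for MT2_Mm, which has 2631 copies. MERVL_2A-int, a related internal part with 3524 copies, had 0.0621 and 0.0686 RPKM, a log2 change of 0.14 that was -0.03 relative to the median family. With 3 families the list's median was the value of MT2_Mm itself, 1.56, or 1.38 relative to the median family, at percentile 100. MERVL-int and MT2_Mm are parts of the same element and can hold the same reads, so this percentile does not rest on independent families. The 24 older ERVL families at the floor had a median of 0.15, which was -0.02 relative to the median family, at percentile 9.62, and 0 of them were 2-fold higher. LTR16D1 and LTR16D2 have under 100 copies and are outside this floor, so they are described by value only: 1.03 and 1.13 RPKM for LTR16D1, and 0.254 and 0.243 RPKM for LTR16D2. LTR33B stood at 0.0294 and 0.0436 RPKM and MLT2B5 at 0.221 and 0.225 RPKM.

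Class I ERVs, which include relatives of murine leukaemia virus and the VL30 and GLN elements, were mostly higher in the Daxx-deleted library. Of 21 families, 19 had a higher value, 10 by at least 1.5-fold and 2 by at least 2-fold. Their median log2 change was 0.57, or 0.39 relative to the median family, at percentile 100. Relative to that family, 16 of the 21 were higher, and 0 were 2-fold higher. The 2 past 2-fold, named after their values were seen, were RLTR4_MM-int, at 0.149 and 0.309 RPKM, and MuRRS-int, at 0.00628 and 0.0141 RPKM, a mean of 0.0102 RPKM that barely passes the floor. RLTR1B-int stood at 2.01 and 3.56 RPKM, a ratio of 1.77, and MuLV-int, the internal part of murine leukaemia virus, at 0.468 and 0.802 RPKM, a ratio of 1.71. RLTR4_Mm, the LTR of a leukaemia virus, stood at 1.12 and 1.52 RPKM. MMERGLN-int, the GLN internal part, had 1.05 RPKM in the control and 0.955 RPKM in the Daxx-deleted library. This was a list that the preset level also reached, with 4 families, a median log2 change of 0.54 at a pseudocount of 0.1 RPKM, and percentile 100. The random lists there were drawn from the rest of the 21 families at that level, so this percentile rests on few values.

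ETn and MusD elements are early transposons and their autonomous relatives. The 5 families had a median log2 change of 0.01, which was -0.17 relative to the median family, at percentile 34.9 of the random lists, and 0 were 2-fold higher or lower. The log2 ratio of their summed RPKM was -0.05, opposite in sign to the median. The 1 family higher by at least 1.5-fold, ETnERV3-int, was named after its value was seen and stood at 0.0119 and 0.0206 RPKM, a ratio of 1.73. ETnERV2-int had 0.664 RPKM in the control and 0.546 RPKM in the Daxx-deleted library, and RLTRETN_Mm had 0.502 and 0.528 RPKM. At the preset level, with a pseudocount of 0.1 RPKM, 3 families remained and their median was 0.01. Relative to the median of the 21 families at that level it was 0.10, at percentile 66.85. The side of the median family on which this list lay therefore depended on the floor. The RLTR9, RLTR13 and RLTR17 LTRs, many of which lie near ES cell enhancers, were close to the median of all families. Their 22 families had a median of 0.24, or 0.06 relative to the median family, at percentile 77.7, and RLTR9E stood at 0.169 and 0.192 RPKM. RLTR17 stood at 0.0558 and 0.0640 RPKM and RLTR9C at 0.0518 and 0.0432 RPKM. RLTR9A2, with 241 copies, was 2-fold lower, at 0.0270 and 0.0119 RPKM.

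**Figure D2:**
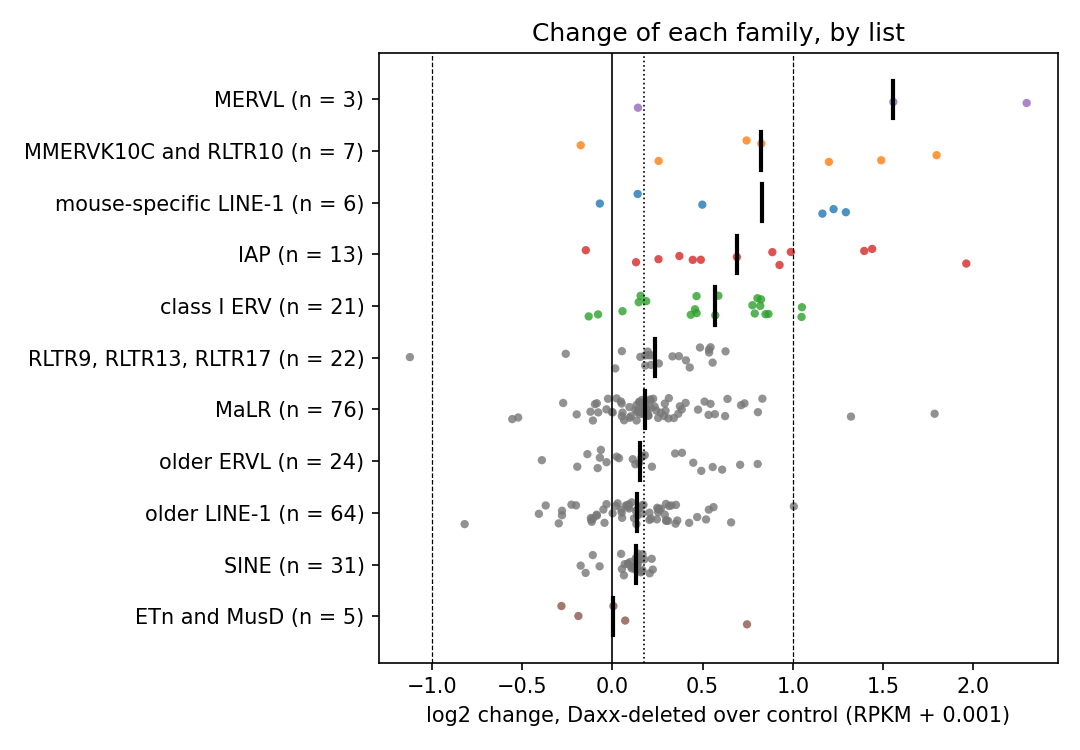
Log2 change (Daxx-deleted over control, RPKM + 0.001; x axis) of each family at the lower floor, grouped by list (y axis, with the number of families). Points are families, short bars are list medians, the dotted line is the median of 436 families (0.18) and the dashed lines mark 2-fold, and the MERVL median stands at 1.56 and the ETn and MusD median at 0.01.

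LINE elements retrotranspose without LTRs. The median of the mouse-specific LINE-1 list was higher than the median family, and that of the older LINE-1 list was not. Of 6 mouse-specific families at the floor, 3 were at least 2-fold higher, and the median log2 change of 0.83 (0.65 relative to the median family) lay at percentile 99.8. L1Md_A stood at 0.0201 and 0.0462 RPKM, a ratio of 2.30, and L1Md_T at 0.0184 and 0.0443 RPKM, a ratio of 2.41. L1Md_Gf, named after its value was seen, stood at 0.0139 and 0.0354 RPKM. After the median family was subtracted, L1Md_A fell just short of 2-fold, at 0.99 on the log2 scale. The differences of L1Md_A and L1Md_T, 0.0261 and 0.0259 RPKM, were small beside the 0.128 RPKM of IAPEz-int. L1_Mus1, with 27181 copies, had 0.0254 and 0.0242 RPKM. The list was split: relative to the median family, 4 of the 6 were higher and 2, L1_Mus1 and L1_Mus2, were lower. L1_Mus2 was named after its value was seen. The result depends on the copies and the pseudocount. With at least 1000 copies the median was 0.50, and with a pseudocount of 0.1 RPKM the median of the 6 families was 0.15. Over all 14 families of the list it was 0.51 with a pseudocount of 0.001 RPKM and 0.03 with 0.1 RPKM, the latter at percentile 35.2. The 64 older LINE-1 families had a median of 0.14, which was -0.04 relative to the median family, at percentile 0.02 of random lists, and the log2 ratio of their summed RPKM was -0.01, opposite in sign to the median. L1M, named after its value was seen, was the 1 family past 2-fold. HAL1 stood at 0.226 and 0.170 RPKM, and L1MEe had 0.238 and 0.254 RPKM. HAL1-2a_MD had 0.621 and 0.505 RPKM.

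SINE families are short elements that are abundant within genes. None of 31 was 1.5-fold higher or lower. Their log2 changes ran from -0.18 to 0.22 with a median of 0.13, which was -0.05 relative to the median family, and 27 of the 31 lay below that family. The percentile was 80.6 among lists matched on level and 5.65 among unmatched lists. The SINE families with the highest levels were lower in the Daxx-deleted library: B2_Mm1a had 0.822 and 0.728 RPKM, B2_Mm1t had 0.423 and 0.382 RPKM, and PB1D9 had 0.319 and 0.296 RPKM. The old elements LFSINE_Vert and MamSINE1, outside that list, had 0.535 and 0.469 RPKM and 0.980 and 0.911 RPKM. MaLR elements, a class III group without genes of their own, had a median of 0.18 over 76 families, or 0.01 relative to the median family, at percentile 29.5. The 2 past 2-fold, MLT1N2 and MLT1B-int, were named after their values were seen. MLT1N2, with 723 copies, stood at 0.00854 and 0.0229 RPKM, and MLT1B-int, with 164 copies, at 0.0102 and 0.0375 RPKM. MTB-int had 0.301 and 0.334 RPKM, MLT1M 0.420 and 0.393 RPKM, and MLT1G1 0.157 and 0.154 RPKM.

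The families with the highest values of the table had few annotated copies, and their differences were below 2-fold. L1M2b, with 18 annotated copies, had 10.1 RPKM in the control and 10.5 RPKM in the Daxx-deleted library. MER34B-int had 5.58 and 5.10 RPKM, and MamGyp-int, derived from an ancient Gypsy-type element, had 5.39 and 4.82 RPKM. MER50B stood at 3.57 and 5.45 RPKM with 12 copies, and LTR45 at 2.88 and 4.16 RPKM with 28 copies. LTR9 had 3.20 and 3.91 RPKM, LTR39 had 2.05 and 1.66 RPKM, and MER50 had 1.74 and 1.52 RPKM. RLTR19-int, a class II ERV with 2528 copies, was lower, at 1.32 and 0.988 RPKM.

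All ratios compare these 2 libraries, and differences between cultures of 1 condition were not measured. Multi-mapped reads were kept, so related families can hold the same reads and the counts within a list are not independent.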

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

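All settings at the lower floor were chosen after the values were seen, and those at the preset floor before. Single libraries give no error, so a value is counted here as moved when it changed by over 1.5-fold, and a percentile when it changed by over 10. At the preset floor of 21 families, the counts of 0 higher and 0 lower at 2-fold were the same with pseudocounts of 0.01 and 1 RPKM, after subtraction of the median, with a floor of 5 RPKM and at 3-fold. They became 2 higher and 1 lower with no floor, and 3 higher and 0 lower at 1.5-fold. No ETn, MusD or class I ERV family reached 5 RPKM, so their medians were not run at that floor. The lower floor gave 23 higher and 2 lower. From there the counts were 11 and 0 with a pseudocount of 0.01 RPKM, 0 and 0 with 0.1 RPKM, 14 and 3 after subtraction of the median, 29 and 7 with no minimum of copies, 10 and 0 with at least 1000 copies, 6 and 0 with a floor of 0.05 RPKM, 66 and 6 at 1.5-fold, and 5 and 0 at 3-fold. The fall with larger pseudocounts follows from their size, since the median family had 0.0209 RPKM in the control. Of the list medians, 97 of the alternative values stayed within 1.5-fold and 3 moved, each with a pseudocount of 0.1 RPKM: MERVL to 0.44, MMERVK10C and RLTR10 to 0.16, and mouse-specific LINE-1 to 0.15. The IAP median was 0.11 there, a difference just under that limit. A median below that limit, 0.58 on the log2 scale, could not be counted as moved by falling to 0, so the tally says little for such lists. The class I ERV median at the lower floor fell from 0.57 to 0.15 with a pseudocount of 0.1 RPKM. Its median at the preset floor fell from 0.54 to 0.13 with no floor, and neither was counted as moved. Without matching on level the percentile of the SINE list was 5.65, of ETn and MusD 6.90, of MaLR 64.6 and of older ERVL 26.4; the IAP, class I ERV, MERVL, MMERVK10C and mouse-specific LINE-1 lists stayed above 99. For the 48 families named by the rule, 169 alternative values stayed within 1.5-fold and 23 moved, all with another pseudocount. The moved values belonged to MERVL-int, MT2_Mm, MMERVK10C-int, RLTR10C, IAPEz-int, IAPEy-int, IAPLTR1_Mm, L1Md_A, L1Md_T, MLT1N2-int and RLTR9A2. Most of these families are among those described as higher. Most of the other named families lay below 0.58 and could not be counted as moved by falling to 0, so this tally says little for them. No paired analysis was possible because each group has 1 library. The unknown depth leaves the counting error of families close to 0.01 RPKM open.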

Other observations

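The tests of explanations, the medians by element part and the spread by copies were chosen after the values were seen. So were the families LTR73, MER110A, MER67A, RodERV21-int, RMER17A-int, RLTR10-int and MER51-int. Of the 23 families 2-fold higher at the lower floor, 16 were in the preset lists and the others were LTR families outside them. Among the others, LTR73, with 154 copies, stood at 0.0069 and 0.0286 RPKM, a ratio of 4.14. MER110A, with 192 copies, stood at 0.0321 and 0.0805 RPKM, and MER67A, with 175 copies, at 0.0076 and 0.0176 RPKM. RodERV21-int, a class I internal part with 1812 copies, stood at 0.00646 and 0.0142 RPKM, and RMER17A-int, a class II internal part with 400 copies, at 0.0110 and 0.0236 RPKM. Medians by part were taken over whole superfamilies. Class I (ERV1) held 56 families at this floor, more than the class I ERV list of 21, with a median log2 change of 0.31. Its 13 internal parts had a median of 0.78 and its 43 LTRs one of 0.22. Families inside and outside that list are mixed here, so a difference between parts was not separated from list membership. In class II (ERVK) the medians were 0.41 for 26 internal parts and 0.22 for the LTRs. ERVL internal parts and LTRs had 0.14 over 7 families and 0.12 over 42 families, and MaLR internal parts and LTRs had 0.17 and 0.19. MIR and L2, ancient elements, had medians of 0.13 over 5 families and 0.13 over 4 families, with 0 families changed by 1.5-fold.

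Among families with a mean of at least 0.01 RPKM, the SD of the log2 change was 0.35 over 257 families with at least 1000 copies and 0.48 over 179 families with 100 to under 1000 copies. Of the 43 with fewer than 100 copies, 5 were listed at 0 in a library, where the pseudocount sets the size of the change. The SD over the other 38 was 0.88, with 3 families 2-fold higher and 3 2-fold lower. MLT1N2-int, with 3 copies, was listed at 0 in the control and at 0.104 RPKM in the Daxx-deleted library, and MER51-int, with 5 copies, at 0.184 RPKM and 0. Of the 21 families above 0.5 RPKM, 9 (42.9%) had under 100 copies, against 95 of the 634 families in the table. The median log2 change was -0.10 in those 21 families with a pseudocount of 0.1 RPKM, and 0.18 at the lower floor with 0.001 RPKM. MamSINE1, the median of those 21, had -0.10 with 0.1 RPKM and -0.11 with 0.001 RPKM, so the pseudocount did not set the sign there. The 0.18 subtracted for values relative to the median family was therefore not the median change of the families above 0.5 RPKM.

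Among families with at least 1000 copies, 10 were 2-fold higher in the Daxx-deleted library, with log2 changes of 1.02 to 2.30: MERVL-int, MT2_Mm, MMERVK10C-int, RLTR10C, RLTR10-int, IAPEz-int, IAPLTR1_Mm, L1Md_A, L1Md_T and RodERV21-int. Scatter of families with few reads would give losses as large as the gains. Each family, relative to the median family, was set against the lowest of the 30 other families nearest in RPKM, with its sign turned. Those 30 came from families outside the 10 with at least 100 copies and were not matched on copies, although the spread differed with copies. For MT2_Mm the lowest was LTR65, with 165 copies. Of the 10, 8 exceeded it by 0.50 or more on the log2 scale, beyond the SD of those 30. MT2_Mm, by 0.28, and RodERV21-int, by 0.15, did not pass that SD and stay open. The 10 were picked for their gains among 257 families, which favours passing, so scatter is not excluded for the 8 either. The outcome also depends on the window: the 30 families nearest to RLTR10-int left out MLT1F-int, with a mean of 0.0243 RPKM and -0.73 relative to the median family. An even background of genomic reads would add a similar RPKM to every family. Unspliced reads need not be even over families, so this comparison does not address them. The median addition in the other 247 families was 0.00410 RPKM. Against a bound of 0.0319 RPKM, the point that 2.5% of those families exceed plus their interquartile range, 6 of the 10 had larger additions, from 0.0320 RPKM in RLTR10C, which barely passes it, to 0.205 RPKM in IAPLTR1_Mm, while the other 4, with at most 0.0261 RPKM, stay open. Loss of Daxx, the hypothesis the design names, cannot be told apart from 4-OHT, Cre activity, feeder share or a difference between the cultures other than Daxx, because there is 1 library per group, and a background concentrated by multi-mapped reads in young families was not tested.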
